A study of Homo sapiens with 8 samples.

How the data were processed

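Gene expression was measured in Kasumi-1, a human acute myeloid leukaemia cell line that carries the t(8;21) translocation and so makes the AML1-ETO fusion protein. Per the labels' protocols, cells were infected with a lentivirus that carried either a short hairpin RNA (shRNA) against PLCG1, the gene of phospholipase C gamma 1, or a scrambled shRNA, were selected with puromycin, and gave RNA 3 days after infection. The labels name 4 samples with each shRNA, and each sample was hybridised to 1 array, 8 arrays in all. Only 1 hairpin against PLCG1 is named for these samples. The labels do not say whether replicates came from separate infections, so that p-values measure the spread between these samples, which may be technical. Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was copied by random priming into Cy3-labelled cRNA, and the cRNA was hybridised to a 1-colour Agilent array designed by Arraystar for human protein-coding and long non-coding RNA (lncRNA) genes.

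The deposited arrays hold intensity values on a linear scale. Per the file headers and the submitters' processing notes, spots were quantified with Agilent Feature Extraction 11.0.1.1, whose processed signal is the spot intensity after background subtraction and detrending within the array, with no scaling between arrays. The submitters' processing notes also name limma without saying for what. The authors' deposited annotation assigns probes to Gencode genes with a symbol and a gene class; how probes were assigned is not given in the sources used here. Per the file headers the array was designed on the hg19 build, and no coordinates are printed.

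Each array held 61464 spots other than controls. Between 51.2% and 58.7% of them were well above background by Feature Extraction's own call, and none was saturated. The 75th percentile of the processed signal ranged from 111 to 145. The number of arrays, rather than a read depth, limits the precision. The file headers place the arrays on 2 slides, scanned separately. Slide 1 held replicates 1, 2 and 3 of both groups and slide 2 held replicate 4 of both. No pair of arrays shared an identical signal at any spot, so each array was counted as 1 sample.

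The log2 of the processed signal minus each array's 75th percentile of it was tested. Control spots were left out, as were 144 spots marked as outliers on any array. A probe counted as detected when it was well above background on at least 4 of the 8 arrays, whatever their group, and each gene was represented by its detected probe with the highest mean signal. This left 30829 genes, of which 15210 were protein-coding, 14726 lncRNA and 893 of other classes. The annotation gave a symbol to 47665 spots; probes without a symbol, which include every probe spotted repeatedly, were left out. Of 1818 genes with more than 1 detected probe, 762 had probes that differed in the sign of their change. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Errors of fold changes are limma's standard errors (SE). A value for a single gene or list per array was also compared with an exact two-sided permutation test over the 70 assignments of the 8 arrays, whose smallest possible p is 0.0286. Where a probe was not well above background on any array of 1 group, the fold is given as a bound: the mean of the brighter group over the mean, per array of the dim group, of the higher of the probe's own value and the lowest value among probes well above background. Levels of different probes were not compared with each other.

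Gene lists, 30 in number, were written from textbook knowledge before the data were examined, as were the groups, the tests, the alternatives to try and the rule for named genes. Of their 1025 members, 999 had a probe, 19 of them through an older or newer symbol in the RefSeq gene table of assembly GRCh38.p14, and 915 passed the filter. A list's shift against all other tested genes was tested with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation, fry of limma, and the exact permutation test of the list's mean per array stand beside it. Of these, fry tests a list against no change rather than against other genes. The rule named PLCG1 and then genes past the threshold with groups that did not overlap; where none passed, the 5 genes with the smallest p. Other genes named as members of lists lie outside this rule and were chosen after their values were seen, as the members with the smallest p: 3 for each list that camera called, and up to 2 that passed when adjusted over the list alone for each other list. Where the text says that a list's members were lower or higher, it gives the sign of the mean change and not a test of each gene.

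The procedure was tested on simulated data with the 30829 genes and the spread of these arrays, with noise drawn independently for each gene. Of 100 genes changed by 1 log2 unit 68 were called, and of 100 changed by 2 log2 units 94 were called, with 8 unchanged genes called. Genes on the real arrays vary together, so these shares need not hold for them. With the preset correlation, a list of 43 genes lowered by 0.25 was called and no other list was. Camera with an estimated correlation was not tried on this list. In 100 further draws with no effect that kept the arrays' own correlation between genes, camera with the preset correlation called a median of 5 lists and at most 14, and called 9 or more in 10 of the draws; with an estimated correlation it called 0 in every draw. The alternatives covered background correction, scaling between arrays, the filter on dim probes, the variance model, array weights, the rule for several probes of a gene, replicate number, slide and scan as blocks, other list tests, and leaving out arrays. A test of 1 further gene list, written after values had been seen, is not reported here but counts in the adjustment over such lists. Figures were drawn with matplotlib.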

Results

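The experiment addressed what a lower level of PLCG1 does to gene expression in t(8;21) leukaemia cells; the study's title places it in work on the self-renewal of AML1-ETO leukaemia stem cells. PLCG1 encodes an enzyme that splits a membrane phospholipid into diacylglycerol, which activates protein kinase C, and inositol trisphosphate, which releases calcium from internal stores. Transcripts of 30829 genes were detected in Kasumi-1 cells on 4 arrays with the scrambled shRNA and 4 with the PLCG1 shRNA.

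PLCG1 itself, the targeted gene (ENSG00000124181, 1 probe), was lower on each of the 4 PLCG1 shRNA arrays than on any scrambled shRNA array. Its processed signal was 70.1 ± 15.9 (SD, n = 4) with the scrambled shRNA and 37.4 ± 6.98 (SD, n = 4) with the PLCG1 shRNA, well above background on all 8 arrays. After scaling it was 1.89-fold lower, with 52.9% of the signal remaining (log2 fold change -0.92 ± 0.16 SE, 95% confidence interval -1.29 to -0.55). The exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. In limma the unadjusted p was 0.000267 and the adjusted p over all genes was 0.126, so PLCG1 did not pass the threshold of the transcriptome-wide test. Within slide 1 the log2 difference was -0.97 and between the 2 arrays of slide 2 it was -0.78; with slide as a block it stayed at -0.92 (limma unadjusted p = 0.000436). Background correction with normexp on the median spot intensities, which adds an offset and compresses dim probes, gave -0.42.

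**Figure D1:**
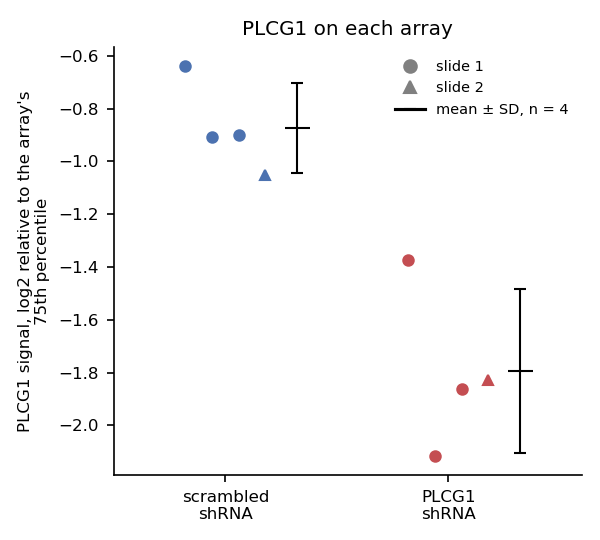
PLCG1 signal on each array, as log2 relative to the array's 75th percentile, for scrambled shRNA and PLCG1 shRNA. Points are arrays, with their slide shown by shape, and bars are the mean ± SD of 4 arrays. The scrambled arrays lie between -1.05 and -0.64 and the PLCG1 shRNA arrays between -2.11 and -1.37.

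The arrays of the scrambled group were not alike. On the first principal component of the tested genes, which held 35.2% of the variance, scrambled replicates 3 and 4 lay at 53.6 and 45.3 and scrambled replicates 1 and 2 at -9.97 and 3.79. The 4 PLCG1 shRNA arrays lay between -28.7 and -15.5. Scrambled replicates 3 and 4 were on different slides. Values without these arrays are given beside the gene groups that moved with them.

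**Figure D2:**
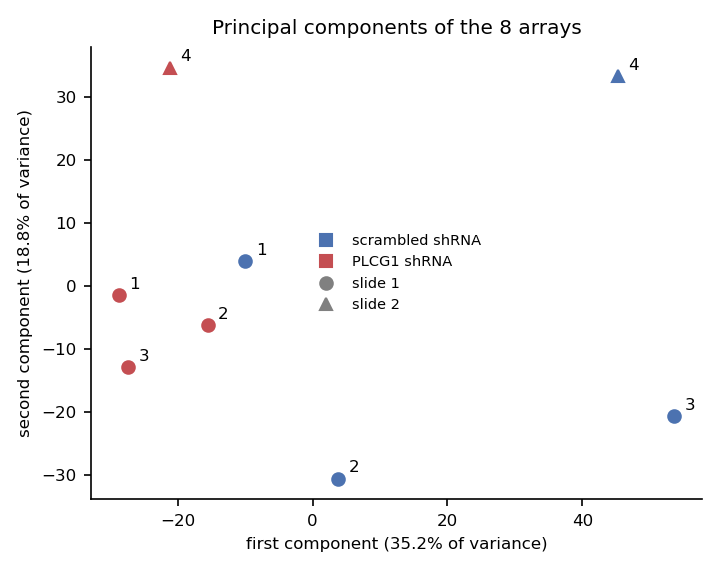
First and second principal components of the 8 arrays over all tested genes, in log2 units, with the replicate number beside each point, the group shown by colour and the slide by shape. The first component holds 35.2% of the variance and sets scrambled replicates 3 and 4 apart from the other 6 arrays; the second holds 18.8% and sets the arrays of slide 2 apart.

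Across the transcriptome, no gene passed the threshold in limma, and the smallest adjusted p was 0.126. At an unadjusted p under 0.05 there were 5091 genes, where 1541 would be expected by chance; 2181 were higher and 2910 lower with the PLCG1 shRNA. This split depended on the scaling: 2533 were higher and 2472 lower under quantile scaling, 2424 and 2592 under cyclic loess scaling, 1911 and 3212 with scaling to the median, and 1786 and 3380 with normexp. The 4 values of each group did not overlap for 3123 genes, which is 10.1% of those tested against 2.86% by chance. The 5 genes with the smallest p were all higher, and none passed (limma adjusted p = 0.126 for each). They were GLTPD2, which encodes a protein with a glycolipid transfer domain (log2 fold change 1.27 ± 0.17 SE, n = 4 per group), and the lncRNA genes AP005131.6 (1.05 ± 0.12), AP005131.7 (1.25 ± 0.17), AC018554.1 (1.00 ± 0.13) and LINC02580. LINC02580 was not well above background on any scrambled array and was at least 1.59-fold higher on the 4 PLCG1 shRNA arrays. The count past the threshold was 67 with normexp on the median spot intensities, 12 genes higher and 55 lower. Without PLCG1 shRNA replicate 2 it was 2, the lysosomal membrane protein gene OSTM1 and the lysozyme gene LYZ, both lower and both named after their values were seen.

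Protein-coding and lncRNA genes went opposite ways. Of the protein-coding genes at an unadjusted p under 0.05, 2332 were lower and 718 higher with the PLCG1 shRNA, so that 76.5% were lower. Of the lncRNA genes, 1405 were higher and 497 lower, so that 73.9% were higher. The median log2 fold change was -0.05 over all protein-coding genes and 0.07 over all lncRNA genes, a difference of -0.12. That difference, taken per array, was lower on each of the 4 PLCG1 shRNA arrays than on any scrambled array (exact permutation p = 0.0286), a comparison chosen after the values were seen. It was -0.15 within slide 1 and -0.03 between the arrays of slide 2. Under quantile and cyclic loess scaling it was -0.07, and 65.1% and 66.6% of the protein-coding genes at an unadjusted p under 0.05 were then lower. With normexp it was -0.06 and the groups overlapped (exact permutation p = 0.114). Leaving out scrambled replicate 3 brought the genes at an unadjusted p under 0.05 from 5091 to 3092, with 1512 protein-coding genes lower and 366 higher and 839 lncRNA genes higher and 298 lower; leaving out scrambled replicates 3 and 4 brought them to 2682. Other single arrays moved parts of this count by over 1.5 times. Without PLCG1 shRNA replicate 1, 449 protein-coding genes were higher; without PLCG1 shRNA replicate 3, 917 lncRNA genes were higher; and without scrambled replicate 1, 850 lncRNA genes were lower.

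Of the 30 gene lists, 9 shifted by camera with the preset correlation, 7 down and 2 up. None of the 9 held when camera estimated the correlation between genes, with adjusted p values from 0.355 to 0.690 that are given list by list. Fry called 2 of them, MYC targets with ribosome biogenesis and the G1/S genes. No member of any list passed the threshold over all genes. With slide as a block all 9 were called, and within slide 1 all but glycolysis were. In simulated data without any effect the preset correlation called 9 or more lists in 10 of 100 draws.

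**Figure D3:**
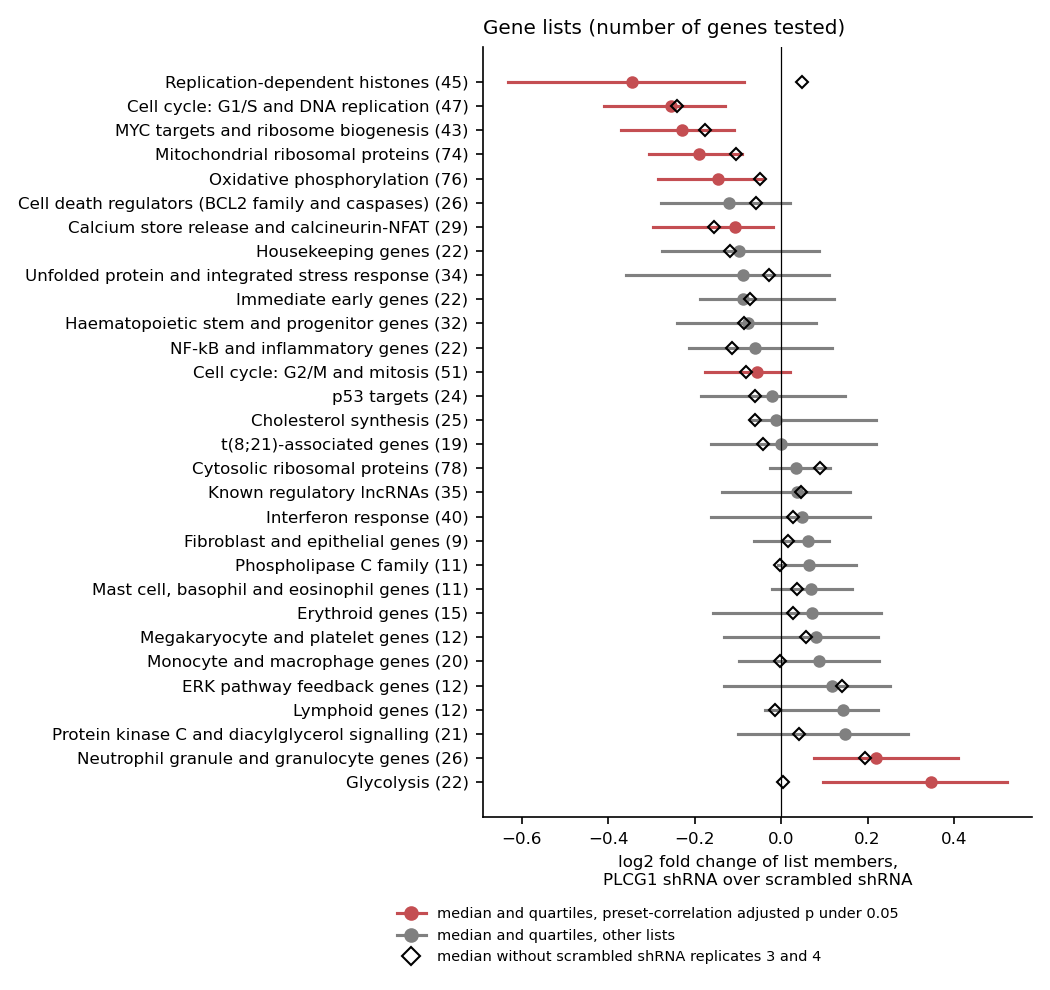
Log2 fold change, PLCG1 shRNA over scrambled shRNA, of the members of each of 30 gene lists, with the number of genes tested in brackets. Filled points are medians and lines reach from the lower to the upper quartile, in red where camera with the preset correlation called the list; open diamonds are medians without scrambled replicates 3 and 4. The histone median lies at -0.34 and at 0.05 without these arrays, and the glycolysis median at 0.35 and 0.00363.

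Growth and replication genes shifted down with the PLCG1 shRNA. Of 43 MYC targets and ribosome biogenesis genes 39 were lower, with a median log2 fold change of -0.23 (camera adjusted p = 3.85e-09; adjusted p = 0.355 with an estimated correlation; exact permutation p = 0.0286), and 10 passed when adjusted over the list alone. Examples are RRS1, a ribosome assembly factor (-0.84 ± 0.13 SE), ODC1, the rate-limiting enzyme of polyamine synthesis (-0.65 ± 0.13), and UTP20, a component of the small-subunit processome (-0.68 ± 0.16). Of 47 G1/S and DNA replication genes 40 were lower, with a median of -0.25 (camera adjusted p = 4.03e-09; adjusted p = 0.355 with an estimated correlation; exact permutation p = 0.0286), and 9 passed when adjusted over the list alone. Among them were UHRF1, which recruits the maintenance DNA methyltransferase (-1.46 ± 0.27, 2.74-fold lower), GINS1 of the replicative helicase (-0.93 ± 0.16) and cyclin E2, CCNE2 (-0.63 ± 0.16). Within slide 1 the medians of these lists were -0.17 and -0.29, and between the arrays of slide 2 they were -0.34 and -0.11. Without scrambled replicates 3 and 4 they were -0.18 and -0.24. Both were weaker under quantile (-0.16 and -0.17) and cyclic loess scaling (-0.14 and -0.17).

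The other replication and mitosis lists shifted less evenly. Camera compares a list with all tested genes, coding and lncRNA together. Protein-coding genes as a whole had a median log2 fold change of -0.05, and those in the brightest of 5 classes of mean signal -0.11. The G2/M list was not compared with coding genes of like signal, so a general shift of such genes stays open for it. Of 51 G2/M and mitosis genes 36 were lower, with a median of -0.06 (camera adjusted p = 0.0445; adjusted p = 0.690 with an estimated correlation); NUSAP1 (-0.60 ± 0.14 SE), the spindle motor KIF11 (-0.52 ± 0.13) and the kinase NEK2 (-0.58 ± 0.15) had the smallest p, and 0 passed when adjusted over the list alone. The sign of this median turned under quantile (0.02) and cyclic loess scaling (0.00803) and between the arrays of slide 2 (0.00448), against -0.10 within slide 1, and the call was lost with normexp (camera adjusted p = 0.0543), with probes well above background on all 8 arrays (0.0780), with array weights (0.103), and without scrambled replicate 1 (0.278), PLCG1 shRNA replicate 2 (0.344) or PLCG1 shRNA replicate 3 (0.151). Of 45 replication-dependent histone genes 37 were lower, with a median of -0.34 (camera adjusted p = 1.60e-05; adjusted p = 0.690 with an estimated correlation; exact permutation p = 0.286). HIST1H2BG (-1.38 ± 0.37), HIST1H3H (-1.07 ± 0.28) and HIST1H2AE (-0.79 ± 0.23) led the list and 0 passed when adjusted over it alone; near-identical histone genes can share a probe's signal. The histone median was -0.28 within slide 1 and -0.84 on slide 2, and without scrambled replicates 3 and 4 it turned to 0.05.

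Mitochondrial lists were also lower. Of 74 mitochondrial ribosomal protein genes 69 were lower, with a median of -0.19 (camera adjusted p = 3.85e-09; adjusted p = 0.496 with an estimated correlation; exact permutation p = 0.0286). MRPL44 (-0.56 ± 0.13 SE), MRPS28 (-0.55 ± 0.13) and MRPL19 (-0.63 ± 0.16) had the smallest p. Of 76 oxidative phosphorylation genes 63 were lower, with a median of -0.15 (camera adjusted p = 8.71e-06; adjusted p = 0.690 with an estimated correlation; exact permutation p = 0.0857), led by the complex I genes NDUFA9 (-0.45 ± 0.13), NDUFAB1 (-0.56 ± 0.17) and NDUFC2 (-0.47 ± 0.16). Adjusted over the list alone, 0 members of either list passed. Medians within slide 1 were -0.14 and -0.07 and on slide 2 -0.36 and -0.40, and without scrambled replicates 3 and 4 they were -0.10 and -0.05. The mitochondrial ribosomal median was weakest under quantile scaling (-0.09), with -0.11 under cyclic loess. The call of the oxidative phosphorylation list was lost without these arrays (camera adjusted p = 0.306), under quantile scaling (0.0697) and under cyclic loess scaling (0.176). The 78 cytosolic ribosomal protein genes were not called, with 53 higher, 25 lower and a median of 0.03 (camera adjusted p = 0.187); they were called as higher within slide 1 (median 0.11), without scrambled replicates 3 and 4 (0.09), under quantile (0.06) and cyclic loess scaling (0.17), with normexp (0.04) and with array weights (0.07), while between the arrays of slide 2 the median was -0.14.

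Glycolysis genes were called as higher, and this list moved with the scrambled arrays that stood apart. Of 22 genes 19 were higher, with a median of 0.35 (camera adjusted p = 0.00219; adjusted p = 0.690 with an estimated correlation; exact permutation p = 0.257). The aldolase gene ALDOC (1.52 ± 0.49 SE), PFKP (0.53 ± 0.20) and pyruvate kinase PKM (0.54 ± 0.25) had the smallest p, and 0 passed when adjusted over the list alone. The list's mean relative to all genes was 3.46 and 3.38 on scrambled replicates 1 and 2 and 2.74 and 2.58 on replicates 3 and 4, against 3.22 to 3.79 on the PLCG1 shRNA arrays. Without scrambled replicates 3 and 4 the median was 0.00363. The median was 0.24 within slide 1, where the list was not called (camera adjusted p = 0.131), and 0.65 on slide 2, and the call was also lost without scrambled replicate 4 (0.0766) or PLCG1 shRNA replicate 1 (0.0637).

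Neutrophil granule and granulocyte genes shifted up. Of 26 tested, 21 were higher, with a median log2 fold change of 0.22 (camera adjusted p = 0.000531; adjusted p = 0.424 with an estimated correlation; exact permutation p = 0.0571). S100A9, a subunit of calprotectin (0.60 ± 0.11 SE, 1.52-fold higher), passed when adjusted over the list alone. The azurocidin gene AZU1 (0.64 ± 0.19) and the adaptor gene LAT2 (0.97 ± 0.27) followed. The median was 0.20 within slide 1, 0.31 on slide 2 and 0.19 without scrambled replicates 3 and 4, and the list stayed called without any single array. Markers of other lineages were not called. Monocyte and macrophage genes (20 tested, 13 higher, median 0.09, camera adjusted p = 0.349) went both ways: adjusted over the list alone, the receptor gene CSF1R (0.69 ± 0.15) passed as higher and the lysozyme gene LYZ (-1.11 ± 0.28) as lower. The medians of the erythroid (0.07), megakaryocyte and platelet (0.08), mast cell, basophil and eosinophil (0.07), lymphoid (0.14), and fibroblast and epithelial genes (0.06) had camera adjusted p values from 0.555 to 0.744. In these lists the transferrin receptor gene TFRC (-0.72 ± 0.16) and EPCAM (-0.36 ± 0.10) passed when adjusted over their list alone.

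**Figure D4:**
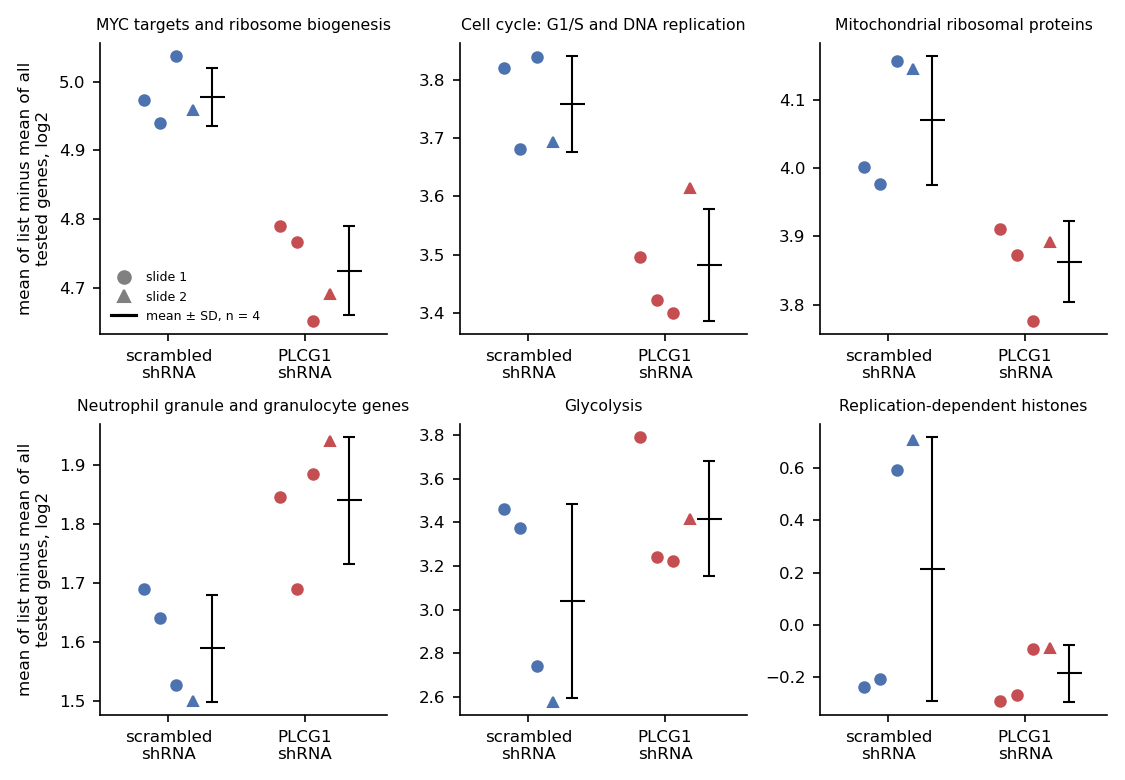
Mean log2 level of 6 gene lists on each array, relative to the mean of all tested genes, for scrambled shRNA and PLCG1 shRNA. Points are arrays with the slide shown by shape, bars are the mean ± SD of 4 arrays, and the vertical axes do not start at 0. MYC targets lie at 4.98 ± 0.04 and 4.72 ± 0.06 without overlap, while glycolysis and histone values of scrambled replicates 3 and 4 lie apart from replicates 1 and 2.

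Stem and progenitor genes lay close to the threshold. Of 32 haematopoietic stem and progenitor genes 19 were lower and 13 higher, with a median of -0.08 (camera adjusted p = 0.0520; adjusted p = 0.496 with an estimated correlation; exact permutation p = 0.0286), so the list was not called. It was called under 7 alternatives: scaling to the median (camera adjusted p = 0.0498), no filter on dim probes (0.0144), trend and robust variances (0.0463), array weights (0.0118), the mean of a gene's probes (0.0370), without scrambled replicates 3 and 4 (0.0274) and within slide 1 (0.0229). Its median was -0.02 on slide 2. Adjusted over the list alone 3 members passed, among them BMI1, a Polycomb gene needed for stem cell self-renewal (-0.61 ± 0.10 SE, 1.53-fold lower), and the transcription factor TAL1 (-0.74 ± 0.15, 1.67-fold lower). The 19 genes associated with t(8;21) were split, 9 lower and 10 higher (median 0.000689, mean -0.04, camera adjusted p = 0.947), with ID1 passing over the list alone (-1.34 ± 0.31, 2.53-fold lower).

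Around PLCG1's own pathway, the calcium store release and calcineurin-NFAT genes were called as lower. Of 29 tested, 22 were lower, with a median of -0.11 (camera adjusted p = 0.0445; adjusted p = 0.690 with an estimated correlation; exact permutation p = 0.0857). The calcium channel gene ORAI2 (-0.41 ± 0.10 SE), the calcineurin regulator RCAN1 (-0.52 ± 0.15) and the store sensor STIM2 (-0.42 ± 0.14) had the smallest p, and 0 passed when adjusted over the list alone. The median was -0.15 within slide 1 and -0.11 on slide 2. Protein-coding genes as a whole had a median of -0.05. Those in the brightest of 5 classes of mean signal had -0.11, and those in the next class -0.06. The calcium list was not compared with coding genes of like signal, so a general shift of such genes stays open for it. The call was lost under quantile scaling (camera adjusted p = 0.127) and cyclic loess scaling (0.125), with probes well above background on all 8 arrays (0.0548), and without scrambled replicate 1 (0.226) or PLCG1 shRNA replicates 1 (0.0503), 2 (0.0520) or 3 (0.220). The other members of the phospholipase C family were not called with PLCG1 (11 tested, 8 higher, median 0.07, camera adjusted p = 0.789), and PLCG1 was the 1 member that passed when adjusted over the list alone. Protein kinase C and diacylglycerol genes (median 0.15, camera adjusted p = 0.349), immediate early genes (-0.09, 0.555) and ERK feedback genes (0.12, 0.534) were not called.

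The remaining lists were not called by camera either. Their medians and adjusted p values were -0.12 and 0.111 for cell death regulators, -0.09 and 0.201 for the unfolded protein response, -0.06 and 0.349 for NF-kB and inflammatory genes, -0.02 and 0.565 for p53 targets, 0.05 and 0.644 for interferon response genes, and 0.04 and 0.644 for known regulatory lncRNAs. Cell death regulators were called as lower with normexp (0.0496) and within slide 1 (0.0494), and the unfolded protein response within slide 1 (0.0292) and without PLCG1 shRNA replicate 4 (0.0198). Among the p53 targets, RRM2B, a ribonucleotide reductase subunit, passed when adjusted over the list alone (-1.11 ± 0.24 SE). Cholesterol synthesis genes had a median of -0.01 but a mean of 0.05, in the direction that camera tested (adjusted p = 0.534), and INSIG1, a sterol-regulated brake on this pathway, passed over the list alone (0.75 ± 0.18). Housekeeping genes, taken as a control list, had a median of -0.10 (camera adjusted p = 0.106) and were called as lower without scrambled replicates 3 and 4 (0.0124), within slide 1 (0.0351) and without PLCG1 shRNA replicate 1 (0.0379); 2 of 22, TFRC and YWHAZ (-0.66 ± 0.15), passed over the list alone.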

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

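Of 174 groups of 4 arrays examined, over the genes and lists named here and the array summaries, 4 held an array far from the other 3 by Dixon's ratio, where chance gives about 8.7. The ERK feedback list averaged 0.98 above all genes on PLCG1 shRNA replicate 4, on slide 2, and 0.57 to 0.58 on the other PLCG1 shRNA arrays (ratio 0.982). GLTPD2 was 0.35 on scrambled replicate 3 and 0.75 to 0.80 on the other scrambled arrays (ratio 0.899). LYZ was 1.06 on scrambled replicate 2 and 1.23 to 1.25 on the other scrambled arrays (ratio 0.906). ODC1 was 3.61 on PLCG1 shRNA replicate 3 and 3.940 to 3.997 on the other PLCG1 shRNA arrays (ratio 0.854).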

How the results depend on the processing

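The alternatives with normexp, cyclic loess, unnamed probes, slide 1 alone, scrambled replicates 3 and 4 left out together, and exact permutation of list means were chosen after seeing the data. Normexp on the mean spot intensity, planned, was not run because the arrays used here give the median instead. PLCG1 stayed lower and short of the threshold under every alternative (adjusted p 0.0630 to 0.529) and without any single array (log2 fold change -1.06 to -0.81). The count past the threshold was 0 under every alternative but normexp, which gave 67 genes (12 higher, 55 lower; 54 protein-coding, 13 lncRNA), and 0 to 2 genes (0 to 2 lower, 0 to 2 protein-coding) without 1 array. The smallest adjusted p with normexp was 0.0492, close to the threshold; the cause was not tested.

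At an unadjusted p under 0.05, leaving out 1 array gave 3092 to 6271 genes, with 1512 to 2589 protein-coding genes lower, 366 to 1076 higher, 839 to 1716 lncRNA genes higher and 298 to 850 lower. Without scrambled replicates 3 and 4 these were 2682, 1095, 308, 1003 and 219, from fewer arrays, and within slide 1, 310 lncRNA genes were lower. Of 30 lists, camera called 7 to 13 under the other settings of the fit, 0 with an estimated correlation, fry 2 and exact permutation 4 at an unadjusted p under 0.05, of which 0 stayed after adjustment (smallest adjusted p 0.214). These 4 lay at the smallest p that the permutation test can give, 0.0286. With so few lists at that floor none can pass adjustment over 30 lists, so the loss says nothing about them. The median turned from -0.06 to 0.0167 (quantile) and 0.00803 (cyclic loess) for G2/M genes, and from -0.34 to 0.0476 for histones without scrambled replicates 3 and 4. Of 1148 values of the 50 other named genes over all settings, 1139 stayed short of the threshold with the same sign. The other 9 came to pass it, with 0 reversed. As no gene passed in the main fit, this count tells little beyond the signs.

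Whether replicate numbers pair the arrays was not tested and stays undecided. Same-numbered arrays correlated at 0.17, -0.04, 0.10 and 0.24 in their deviations from the group means. Of the 8 arrays, 4 correlated best with their own number. Both arrays numbered 4 also shared a slide. With the replicate block 0 genes passed, 5008 had an unadjusted p under 0.05, PLCG1 stayed at -0.92 and 9 lists were called. With slide or scan, which part the arrays alike, as a block these were 0, 5650, -0.92 and 9. Signal over background limited what was tested: without any filter, values of dim probes add genes whose change cannot be measured.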

Other observations

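The lists of heat shock chaperones, ID family genes and hypoxia-induced genes were written after some of their members had been seen, and the tests on them, on slide, array brightness and labels, on signal, on lists against their neighbours in signal, and within classes of GC were chosen after the result was seen; the tests on a smooth fit on probe GC, on scrambled replicates 3 and 4 as a source, on matched random lists and on other splits of the arrays were set before their results were seen.

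Heat shock chaperones were lower with the PLCG1 shRNA. Of 20 genes, 18 were lower, with a median log2 fold change of -0.32, and 8 passed when adjusted over the list alone, among them HSPA1B (-1.35 ± 0.30 SE), HSPH1 (-0.58 ± 0.13) and DNAJB1 (-0.54 ± 0.15). The members HSPA1A and HSPA1B had prompted the list. Over the other 18 the mean per array, relative to all tested genes, was lower on all 4 PLCG1 shRNA arrays (exact permutation p = 0.0286, unadjusted). These 18 were read on the same arrays and members of the list vary together, so they are not independent support. Protein-coding genes in the brightest of 5 classes of mean signal had a median of -0.11. The chaperone list was not compared with coding genes of like signal, so a general shift of such genes stays open for it. For the whole list, adjusted over the lists written after values were seen, the exact permutation p was 0.0571 and the camera p with an estimated correlation 0.0968, both short of the threshold; fry (adjusted p = 0.00484) and camera with the preset correlation (5.84e-08) passed. The members' estimated correlation was 0.20, above the preset. The median was -0.21 within slide 1, -0.44 on slide 2 and -0.26 without scrambled replicates 3 and 4, and lay between -0.33 and -0.20 under the scalings tried.

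All 4 ID genes, whose proteins block DNA binding by basic helix-loop-helix factors, were lower, with ID3 at -1.87 ± 0.38 SE, ID1 at -1.34 ± 0.31, ID4 at -1.04 ± 0.21 and ID2 at -0.76 ± 0.21; all were past the list alone and none past all genes (limma adjusted p 0.126 to 0.156). ID2 was the 1 member not seen before the list was written (exact permutation p = 0.0286), so that no test of the family as a set is left.

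Scrambled replicates 3 and 4 lay apart from replicates 1 and 2. On the first component the gap between replicates 3 and 4 was 0.167 of the gap from replicate 3 to the nearer of the others. These arrays were picked for lying together there, so this ratio is no test. They were on different slides, while replicate 3 shared its slide with replicates 1 and 2, which argues against slide. Their numbers of probes well above background differed by 3849, while replicate 3 lay within 133 of replicate 2. The median signal, though, was 17.3 and 17.2 on replicates 3 and 4 and 20.7 and 20.1 on replicates 1 and 2, so brightness stays open, under a rule widened after these medians were compared; PLCG1 shRNA replicate 1, at 17.6, lay at -28.7 on the first component, but is a single array. PLCG1 on both lay at least 0.32 above the highest PLCG1 shRNA array (SD in that group 0.31), which argues against a swapped label. Of 22 hypoxia-induced genes not yet seen, 68.2% were lower on both arrays than on both others, against 26.3% of all protein-coding genes and at most 63.6% in 10000 random lists matched on mean signal. Such random lists do not move together as these genes do, so the comparison is loose. The 22 genes were also read on the same arrays as the members already seen. Members of the whole list vary together (estimated correlation 0.44), and these arrays were picked for standing apart. The share is thus not independent support. Between the groups the whole list was higher with the PLCG1 shRNA for 27 of 32 genes, with a median of 0.31 (camera adjusted p = 0.000229 over the lists written after values were seen; 0.451 with an estimated correlation; fry 0.30; exact permutation p = 0.2), and 0.06 without scrambled replicates 3 and 4. The share is in line with a candidate explanation that the cultures differed in oxygen or density; no label records either, and no biological explanation that the design names was tested.

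Protein-coding genes were lower and lncRNA genes higher with the PLCG1 shRNA, and 1 of the 35 splits of the arrays into 4 and 4, the real one, gave a difference as large (0.12 against at most 0.11 in another split). This is the smallest share 35 splits can give, and the comparison was chosen after the values were seen, so chance is not ruled out for it. Within 5 classes of mean signal the difference averaged -0.0916, from -0.04 in the dimmest to -0.15 in the brightest. After cyclic loess it was -0.07 (exact permutation p = 0.0286). With normexp, which compresses the changes of dim probes, it was -0.06 (exact permutation p = 0.114). Scaling that depends on signal may thus account for part of the difference. Whether it accounts for the whole is not settled, as signal can still differ within a class. The difference was -0.12 after a smooth fit on probe GC, whose fitted values ran from -0.14 to 0.03. Coding and lncRNA genes had similar median GC (45% and 43.3%), so this fit could move the difference little. Within 5 classes of like GC it was -0.19 in the lowest class, -0.20 in the next and -0.05 in the highest. It was negative in every class, which argues against GC as its whole source, but its size depended on GC. Without scrambled replicates 3 and 4 the difference was also -0.12, which argues against these arrays. An effect of the hairpin and a difference in RNA quality or ribosomal RNA removal between the groups stay open, untested.

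MYC-target, replication and mitochondrial lists were lower, while cytosolic ribosomal proteins were not (median 0.03). Tests of possible sources gave results that differed by list, but no test compared the sources of the lists with each other. Against 10000 random protein-coding lists matched on mean signal, the medians of MYC targets and ribosome biogenesis (percentile 0.14), G1/S genes (0), mitochondrial ribosomal proteins (0.47) and histones (0) lay below nearly all, and that of oxidative phosphorylation (7.75) did not. Such random lists do not move together as list members do (estimated correlations 0.10 to 0.55), so a low percentile alone excludes nothing. Each list's mean per array minus that of coding genes of like signal was permuted over arrays. It gave -0.15 for MYC targets, -0.18 for G1/S genes and -0.11 for mitochondrial ribosomal proteins. The exact permutation p was 0.0286 for each, and 0.0476 adjusted over these 5 lists. The 5 were picked because the same arrays called them, so these p values are not independent support. On these arrays MYC targets, G1/S genes and mitochondrial ribosomal proteins fell further than coding genes of like signal, but chance is not excluded. Histones (-0.35, exact permutation p = 0.343) and oxidative phosphorylation (-0.05, 0.314) were not set apart from such genes. A general shift of bright coding genes thus stays open for them, and is not excluded for the others. Without scrambled replicates 3 and 4, MYC targets kept 76.8% of their median and G1/S genes 94.6%, which argues against these arrays as the source; oxidative phosphorylation kept 33.2% and histones -13.8%, in line with them, and mitochondrial ribosomal proteins (55.1%) stay undecided. For the number of lists chance is not excluded: 6 of the 35 splits gave 9 or more, and the highest other gave 13. An effect of the single hairpin on other genes stays open for all these lists, as no other hairpin was tested here.

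The count of 0 genes past the threshold was reached by all 35 splits, as every split must reach it, so it says nothing about chance; the highest other split gave 1 gene. The 5091 genes at an unadjusted p under 0.05 were reached by 1 split, the real one, against at most 3574 in another. This share, 0.0286, is the smallest that 35 splits can give. The count was 1 of several measures taken over the same splits, with no adjustment for their number. The splits also took no account of slide, so chance is not ruled out for the count. The count also leaned on single arrays, with 3092 genes without scrambled replicate 3 and 2682 without replicates 3 and 4.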
